A study of Mus musculus with 6 samples.

How the data were processed

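Gene expression was measured on Affymetrix whole mouse genome arrays, 1 per sample, with biotin-labelled total RNA. The cells were E14Tg2a.4, a mouse embryonic stem cell line, grown in M15 medium on plates coated with gelatin. They were transfected by lipofection and harvested on day 4. The 6 arrays form 3 groups of 2: Fip1 siRNA 2, Fip1 siRNA 3 and a mock group. The mock group received the transfection reagent without any siRNA, so no group carries a non-targeting siRNA. The labels do not say whether the replicates of a group came from separate cultures. The p-values measure the spread between these samples, which may be partly technical.

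The deposited values are log2 probe set values made with RMA, per the submitters' processing notes. RMA subtracts background, normalizes between arrays and summarises the probes of a probe set into 1 log2 value. Its version, settings and probe set definition are not given in the sources used here, and the probe positions were not used here. The array medians of the log2 values lay between 6.08 and 6.12, so no further scaling was applied. RMA compresses changes near the background and near saturation. No detection calls were used, and the number of arrays limits the precision.

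The table holds 16556 probe sets. A platform annotation gave 1 gene for 15270 of them and several genes for 0. The other 1286 are unnamed here and entered only an additional fit. All 15270 gene numbers were found in a mouse gene table of assembly GRCm38.p6, which was used only for names. For 3 genes with 2 probe sets the brighter one was kept, which left 15267 genes. No filter on dim probe sets was used. Every column of the table belongs to 1 of the 6 samples.

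The tests used limma 3.58.1 in R 4.3.3. One linear model with 3 group means was fitted to all 6 arrays (3 residual degrees of freedom), followed by empirical Bayes moderation with a trend of the prior variance over the mean level. The contrasts were the mean of both siRNAs minus mock, each siRNA minus mock, and siRNA 2 minus siRNA 3. The p-values are two-sided and were adjusted by Benjamini-Hochberg over 15267 genes, with a threshold of 0.05. Fold changes are on the log2 scale with the standard error (SE) of the model. Confidence intervals cover 95%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

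Before the data were examined, 17 gene lists were fixed: cleavage and polyadenylation factors, pluripotency genes, markers of the post-implantation epiblast, trophectoderm, primitive endoderm, mesoderm, neuroectoderm, fibroblasts and the 2-cell-like state, cell cycle genes, p53 targets, interferon response genes, genes of the unfolded protein and integrated stress responses, sterol synthesis genes, ERK feedback genes, replication-dependent histones and ribosomal proteins. Fip1l1 is in no list, and Sesn2 is in the p53 and stress lists. Lists were tested against all other genes with camera at a preset inter-gene correlation of 0.01, adjusted over the 17 lists. Camera with an estimated correlation and fry stand beside it. The estimated version refers its statistic to the residual degrees of freedom (3, or 2 with the block), so a small p is hard to reach. Fry tests whether the genes of a list move in one direction on balance and does not compare the list with other genes.

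The genes named in the text follow a rule fixed at the same time. It takes Fip1l1, and the 10 largest rises and 10 largest falls among genes past the threshold for the mean of both siRNAs. All 4 differences between a siRNA array and the mock array of the same replicate number had to share the sign of the contrast. It takes 5 in each direction by the same rule for each siRNA and for the difference between the siRNAs. If none passed, the 5 with the smallest p in each direction were taken and are said not to pass. Gene models without a regular symbol, microRNA genes and small nucleolar RNA genes were left out. It also takes up to 4 members of each list, members past the threshold first and the larger changes first, and 11 fixed marker genes whatever their values. Brachyury is 1 of these and was not analysed here. Genes named outside the rule are said to be so.

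Samples with the same replicate number share a suffix in their titles across the 3 groups. Their deviations from the group means were correlated over genes at 0.383 (siRNA 2 with siRNA 3), 0.281 (siRNA 2 with mock) and 0.443 (siRNA 3 with mock). The replicate numbers were therefore taken to pair the samples. The main model was fixed without the replicate number. A second fit has the replicate number as a block (2 residual degrees of freedom), and its value is printed where it changes a call or moves a count by more than 1.5 times. Pairs of arrays correlated at 0.986 to 0.997, and none were near-identical.

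The model was tested on simulated data with the spread of the real arrays. Of 200 genes changed for the mean of both siRNAs, 67.5% were recovered at a 1.5-fold change, 99.0% at 2-fold and 99.5% at 4-fold, with 9 to 12 false calls among 15267 genes. The comparisons with each siRNA share the mock arrays, so unchanged groups against shared mock arrays were simulated in 100 draws for the correlation and 20 for the overlap of calls. The alternatives covered the replicate block, probe sets per gene, filters at the 25th and 50th percentile of level, repeated quantile normalization, median centring, the empirical Bayes prior, 32 units added before the logarithm, leaving out each array in turn, the 4 siRNA arrays as 1 group, a 2-fold minimum, only the arrays compared, and the list tests.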

Results

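The data collected are 6 expression arrays of mouse embryonic stem cells in which Fip1 was depleted with either of 2 siRNAs or which were mock transfected, with 2 arrays in each group. Fip1, encoded by Fip1l1, is a subunit of the cleavage and polyadenylation specificity factor, the complex that recognises poly(A) signals at the 3′ ends of transcripts. The study examined mRNA levels after Fip1 depletion, within work on alternative polyadenylation and stem cell self-renewal. Each array gave 16556 log2 values with a median between 6.08 and 6.12.

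Fip1l1 mRNA was lower on every siRNA array than on both mock arrays. Its log2 value was 9.65 and 9.74 on the mock arrays, 8.26 and 7.79 with siRNA 2, and 8.39 and 7.86 with siRNA 3 (replicates 1 and 2). The mean of both siRNAs minus mock was -1.62 (SE 0.177, limma adjusted p = 0.00176, 95% interval -2.02 to -1.22), which left 32.5% of the mock level. The remaining level was 31.4% with siRNA 2 and 33.7% with siRNA 3. Against the mock array of the same replicate number, 38.2% and 41.8% remained in replicate 1 and 25.9% and 27.1% in replicate 2.

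**Figure D1:**
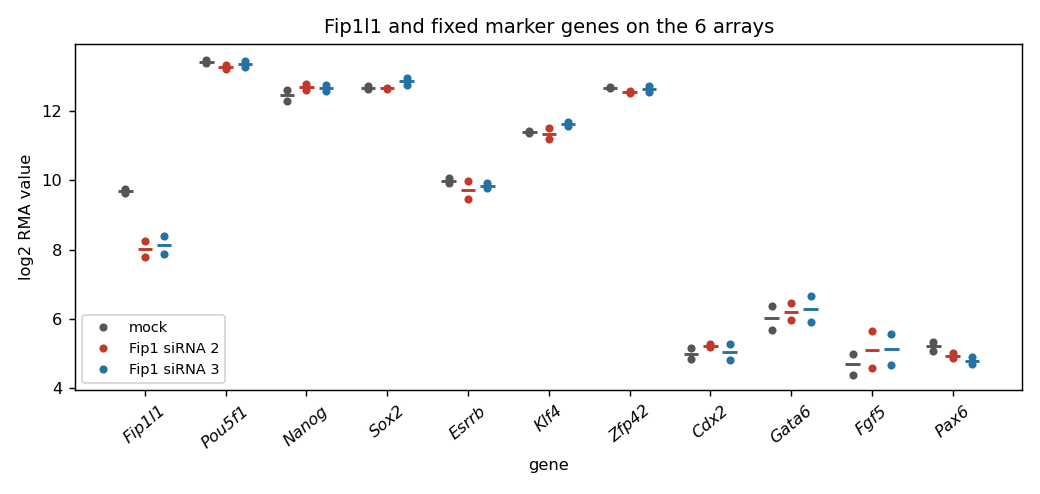
Log2 RMA value of Fip1l1 and of 10 fixed marker genes (horizontal axis) on the 6 arrays; points are arrays, lines are the means of 2 arrays, and colours mark mock, Fip1 siRNA 2 and Fip1 siRNA 3. Fip1l1 lies at 9.65 and 9.74 on the mock arrays and between 7.79 and 8.39 on the siRNA arrays, while none of the other genes shown passed the test.

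The first comparison asked which mRNAs differ after Fip1 depletion, as the mean of both siRNAs against mock. Probe positions were not used here, so for any gene below an altered transcript end cannot be told apart from a change in mRNA level. Atp5g1, which encodes the membrane ring subunit of mitochondrial ATP synthase, rose most, by 2.84 on the log2 scale (SE 0.161, 7.17-fold, adjusted p = 0.000473). Foxa1, a forkhead transcription factor of endoderm, rose 4.88-fold. Cryab, a small heat shock protein, rose 4.58-fold, and Bhmt, an enzyme of methionine metabolism, rose 4.25-fold. The other large rises were those of the ribosomal protein gene Rps15a (4.14-fold), the gluconeogenic enzyme Fbp2 (4.05-fold), the RNA-binding protein Hnrnpd (3.88-fold), Ccdc113 (3.8-fold), Zfp352 (3.68-fold) and Phlda1 (3.63-fold). Lpcat3, an acyltransferase of phospholipid remodelling, was 4.72-fold lower (log2 change -2.24, SE 0.225, adjusted p = 0.00168). Tex14, required for intercellular bridges of germ cells, was 4.50-fold lower, the mitochondrial enzyme Clybl 4.07-fold, the tubulin-binding protein Stmn2 3.89-fold and the formin Diaph2 3.79-fold. Mettl23 (3.65-fold), the formin Fhod3 (3.65-fold), the testis-specific proteasome subunit Psma8 (3.52-fold), the pyridoxal kinase Pdxk (3.27-fold) and the mitochondrial acetyl-CoA synthetase Acss1 (3.23-fold) were the other large falls. The adjusted p of these 20 genes lay between 0.000473 (Atp5g1 and Clybl) and 0.0153 (Bhmt). The call of Bhmt ended without mock replicate 1 (adjusted p = 0.0982) or mock replicate 2 (0.0783), and that of Tex14 without mock replicate 2 (0.0659).

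In all, 1578 of the 15267 genes passed the threshold (10.3%), of which 633 were higher and 945 lower after depletion. The split was 723 and 829 after median centring and 715 and 826 after repeated quantile normalization. Each of the 1578 changed in the same direction in all 4 differences between a siRNA array and the mock array of its replicate number, which selection by the mean of the same arrays favours. A change of at least 2-fold was found for 244 of them, 109 higher and 135 lower. With the replicate number as a block, 3080 genes passed (1287 higher, 1793 lower), among them all 1578. The count was 305 without mock replicate 2, 948 without mock replicate 1, 994 without siRNA 2 replicate 1 and 757 without siRNA 2 replicate 2.

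Pluripotency genes changed in both directions, and the core factors did not pass. Of 25 measured genes in the pluripotency list, 1 rose, 2 fell and 22 did not pass, where 10.3% of all genes tested passed. The median level of the list was 11.2, and at levels of 9 to 13 the share that passed was 16.1%, ribosomal protein genes left out. Dppa3, a maternal factor and naive-state marker, fell by 0.91 (SE 0.150, adjusted p = 0.00844), and Tcl1, a cofactor of Akt, fell by 0.54 (SE 0.124, adjusted p = 0.0295). Dppa2 rose by 0.30 (SE 0.0679, adjusted p = 0.0278). For the core factors the log2 difference was -0.11 for Pou5f1 (SE 0.0759), 0.22 for Nanog (SE 0.105), 0.08 for Sox2 (SE 0.0742), -0.20 for Esrrb (SE 0.140), 0.10 for Klf4 (SE 0.101) and -0.09 for Zfp42 (SE 0.0744). Tbx3 had a difference of 0.48 (adjusted p = 0.123). With the replicate block 5 genes of the list were higher and 6 lower, with an adjusted p of 0.0312 for Nanog and 0.0114 for Tbx3. As a set the list was not shifted (camera adjusted p = 0.612). The call of Dppa3 ended without mock replicate 1 (adjusted p = 0.0558), and those of Tcl1 and Dppa2 without either mock array or either siRNA 2 array (0.0522 to 0.223), and that of Dppa2 also without siRNA 3 replicate 2 (0.072). Tbx3 passed without siRNA 2 replicate 1 (0.0356).

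Single markers of differentiated lineages changed, while camera called none of the 6 lists of more than 1 measured gene. Of all genes tested 10.3% passed, so a few calls in a list do not by themselves set it apart. That share depends on level: at levels of 9 to 13 it was 16.1%, ribosomal protein genes left out. The median levels of these 6 lists ran from 4.33 (fibroblasts) to 7.34 (post-implantation epiblast), and the share at such levels was not computed. In the trophectoderm list, 2 of 18 measured genes rose, Eomes by 1.02 (SE 0.157, adjusted p = 0.00664) and Gata3 by 0.82 (SE 0.129, adjusted p = 0.00697), and Ascl2 fell by 0.78 (SE 0.150, adjusted p = 0.0152); Cdx2 had a difference of 0.13 and Krt8 of 0.68, which did not pass. In the mesoderm list, 3 of 15 rose and 0 fell: Kdr, the VEGF receptor, by 0.96, Evx1 by 0.69 and Gsc by 0.58, while Snai2 did not pass (0.32). In the post-implantation epiblast list, 1 of 15 rose, Nodal by 0.78 (SE 0.0934, adjusted p = 0.00246), while Lef1 (-0.82), Otx2 (0.71) and Fgf5 (0.43) did not pass. In the primitive endoderm list, 1 of 18 rose, Sparc by 0.67, while Gata6 (0.21), Cubn (-1.19), Amn (-0.80) and Sox17 (-0.40) did not pass. In the neuroectoderm list, Zic1 rose by 0.76, Stmn2 fell by 1.96 and 12 of 14 did not pass, Pax6 (-0.35) and Ncam1 (-0.36) among them. No gene of the fibroblast list passed in limma (0 of 14, 1 with the block); Vim had a difference of 0.36, Thy1 of 0.18, Pdgfrb of -0.14 and Postn of 0.12. Of the 10 fixed genes of the 2-cell-like list only Zfp352 was measured, and it rose by 1.88. In the mock group the mean level was 3.64 for Gsc, 3.64 for Zic1 and 4.15 for Gata3. These lie below the 25th percentile of the mock arrays (4.18 and 4.25), and without detection calls their expression in mock is uncertain. Eomes (6.55), Kdr (5.36) and Evx1 (5.08) lay above it.

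The camera adjusted p was 0.0798 for the trophectoderm list, 0.221 for mesoderm, 0.657 for epiblast, 0.642 for primitive endoderm and for neuroectoderm, and 0.612 for fibroblasts. For the single gene of the 2-cell-like list it was 0.0106. The version with an estimated correlation gave 0.276. A single gene has no correlation to estimate, so that value reflects the fewer degrees of freedom. The mesoderm and neuroectoderm medians (-0.0331 and 0.0254) had the opposite sign to their means (0.15 and -0.124) and tests. Fry, which does not compare a list with other genes, called mesoderm higher and neuroectoderm lower (adjusted p = 0.0188 for each). With the replicate block the trophectoderm list passed (adjusted p = 0.0376, or 0.325 with an estimated correlation), and so did Krt8 (0.0102), Lef1 (0.000902), Otx2 (0.00841), Fgf5 (0.0402), Cubn (0.00153), Amn (0.0456), Sox17 (0.048) and Vim (0.0301). The block gave 4 higher and 1 lower for trophectoderm, 3 and 2 for epiblast, and 1 and 3 for primitive endoderm. Adjusted over the list alone, the counts were the same for these lists except the epiblast list, with 2 higher and 1 lower. Kdr, Nodal, Stmn2 and Zfp352 kept their calls without any 1 array; without mock replicate 2 Eomes, Gata3, Ascl2, Evx1, Gsc and Zic1 did not pass (adjusted p 0.0658 to 0.229). Without siRNA 2 replicate 2 Ascl2, Evx1, Gsc and Zic1 did not pass (0.0523 to 0.121), nor did Gsc and Sparc without mock replicate 1 (0.214 and 0.0769), Zic1 without siRNA 2 replicate 1 (0.0839) and Gsc without siRNA 3 replicate 2 (0.0877). Otx2, Cubn and Amn passed without mock replicate 1 (0.00797, 0.0113 and 0.00573), Lef1 without siRNA 3 replicate 1 (0.0268) and Cubn without siRNA 3 replicate 2 (0.044). The trophectoderm list passed without siRNA 2 replicate 2 (0.0322) or siRNA 3 replicate 2 (0.0364), and the epiblast list (mean 0.339, adjusted p = 0.0458) and the primitive endoderm list (mean -0.35, adjusted p = 0.0472) passed without mock replicate 1. Without mock replicate 2 the means of the latter 2 lists had the opposite sign (-0.175 and 0.0978) and did not pass, and with all arrays their adjusted p was 0.913 and 0.91 with an estimated correlation.

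**Figure D2:**
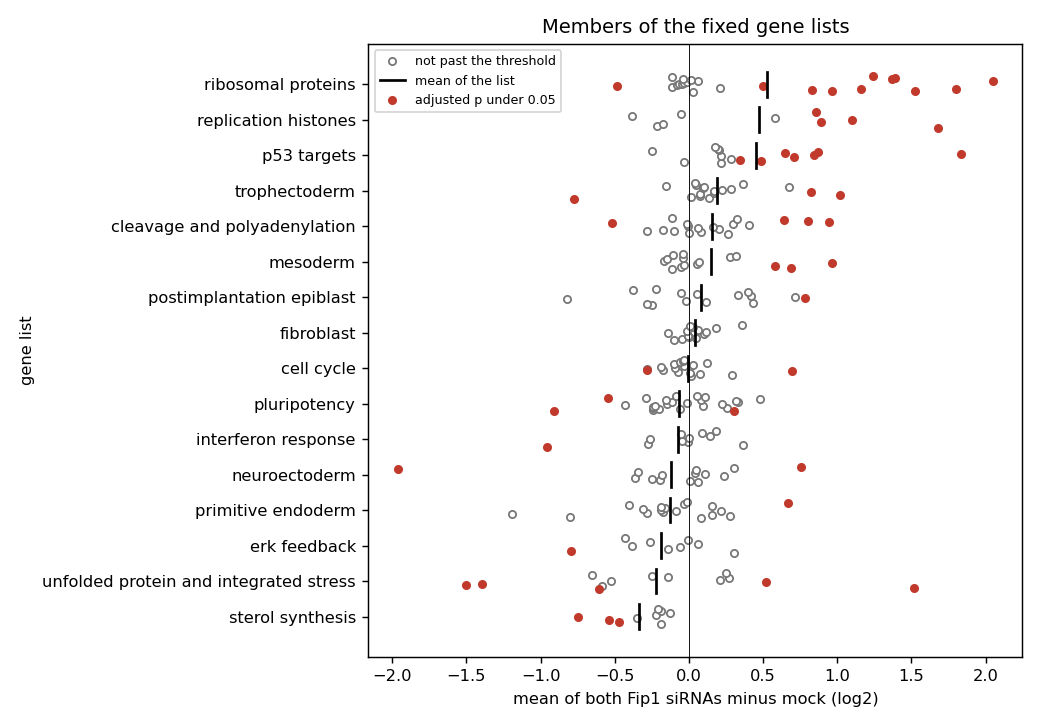
Log2 difference (mean of both Fip1 siRNAs minus mock, horizontal axis) of each measured member of 16 fixed gene lists (vertical axis); filled points passed an adjusted p of 0.05, open points did not, and black lines are list means. The ribosomal protein list holds 10 filled points above 0 and 1 below, the p53 list 7 above 0, and the sterol synthesis list 3 below 0.

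Genes of the 3′ end processing machinery and of 2 other abundant RNA classes were among those that changed. Of 19 measured cleavage and polyadenylation factors, 3 rose: Pcf11, a termination factor that binds the RNA polymerase II tail, by 0.94 (SE 0.0964, adjusted p = 0.00168), Rbbp6 by 0.80 (SE 0.144, adjusted p = 0.0119) and the phosphatase Ssu72 by 0.64 (SE 0.0691, adjusted p = 0.00176). The poly(A) polymerase Papolg fell by 0.52 (SE 0.0912, adjusted p = 0.0111), and 15 did not pass. Adjusted over the list alone, 6 were higher and 2 lower. Of 23 ribosomal protein genes, 10 rose and 1 fell. Rps15a rose by 2.05, Rpl21 by 1.80, Rpl14 by 1.53 and Rps6 by 1.39 (SE 0.101 to 0.153, adjusted p 0.00052 to 0.0011). The gene that fell was Rpl39l, a paralogue with testis-biased expression, by 0.48; it is named after its value was seen. Of 9 replication-dependent histone genes, 4 rose: H1f2 by 1.68, H3c14 by 1.10, H2bc4 by 0.89 and H4c9 by 0.86 (adjusted p 0.0022 to 0.021). Both last counts were the same when adjusted over the list alone. Ribosomal protein and histone genes have near-identical copies and pseudogenes, so their probe sets may read more than 1 gene.

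The ribosomal protein list was shifted upwards (camera adjusted p = 0.000102, or 0.276 with an estimated correlation). Its mean was 0.528 and its median 0.0611, and the median was 0.0625 in replicate 1 and 0.0626 in replicate 2. The cleavage factor list (adjusted p = 0.0582) and the histone list (0.0668) did not pass. With an estimated correlation their adjusted p was 0.276 and 0.557, and fry called the cleavage factor list higher (adjusted p = 0.0143). The cleavage factor list passed camera after repeated quantile normalization (adjusted p = 0.0371). The histone list (mean 0.476) passed without genes under the 25th percentile of level (mean 0.668, adjusted p = 0.0164) and without genes under the median level (mean 1.02, adjusted p = 0.0011). With the replicate block the histone list passed (adjusted p = 0.0289, or 0.325 with an estimated correlation), and 6 cleavage factors were higher and 2 lower. Pcf11, Ssu72, H1f2 and the 4 ribosomal protein genes kept their calls without any 1 array. Without mock replicate 2, Rbbp6, Papolg, Rpl39l, H3c14, H2bc4 and H4c9 did not pass (adjusted p 0.0501 to 0.129). Rbbp6, H3c14, H2bc4 and H4c9 did not pass without mock replicate 1 (0.0539 to 0.0987), nor H3c14 and H4c9 without siRNA 2 replicate 2 (0.054 and 0.0535). The cleavage factor list passed without siRNA 2 replicate 2 (0.0322), siRNA 3 replicate 2 (0.0295) or mock replicate 1 (0.032), and the histone list without either siRNA 3 array (0.0113 and 0.0295) or mock replicate 2 (0.00658).

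**Figure D3:**
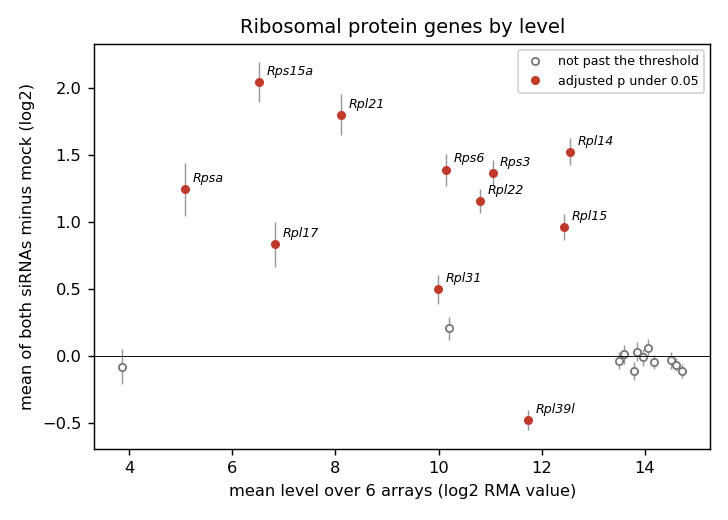
Log2 difference of 23 ribosomal protein genes (vertical axis, mean of both siRNAs minus mock, bars are the SE) against their mean level over the 6 arrays (horizontal axis, log2 RMA value). The 10 genes above a level of 13 lie within 0.115 of 0 and did not pass, and the 10 genes that rose lie below that level.

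Genes among the targets of the tumour suppressor p53 rose, and genes of sterol synthesis fell. Of 15 measured p53 targets (18 were fixed), 7 rose, 0 fell and 8 did not pass, and 13 had a positive difference. Cdkn1a had a difference of 0.28 and did not pass (limma adjusted p = 0.163, or 0.0553 with the block). The differences of Bbc3 (-0.03) and Sesn2 (-0.25) were negative and did not pass. These 3 genes are named outside the rule. Perp, a membrane protein of p53-dependent apoptosis, rose by 1.83 (SE 0.0998, 3.57-fold, adjusted p = 0.000473), the kinase Plk2 by 0.87, Mdm2, the ubiquitin ligase of p53, by 0.84 and Ei24 by 0.71. The list was shifted upwards (camera adjusted p = 8.62e-07, or 0.276 with an estimated correlation), with a median of 0.299 in replicate 1 and 0.315 in replicate 2. Of 9 measured sterol synthesis genes, 3 fell and 0 rose: Lss by 0.75, Fdft1 by 0.54 and Dhcr7 by 0.47 (adjusted p 0.00701 to 0.018), and all 9 had a negative difference. Insig1, a feedback regulator of the pathway, had a difference of -0.35 and did not pass (adjusted p = 0.108, or 0.0356 with the block). That list was shifted downwards (camera adjusted p = 0.00184, or 0.276 with an estimated correlation), with a median of -0.203 in replicate 1 and -0.281 in replicate 2. Adjusted over the list alone, 4 sterol genes were lower, and the p53 counts were the same. Without mock replicate 2, 3 p53 targets passed. Ei24 did not pass without that array (adjusted p = 0.0513), Lss, Fdft1 and Dhcr7 without it (0.0713 to 0.142), Fdft1 and Dhcr7 without mock replicate 1 (0.0756 and 0.0661), and Dhcr7 without either siRNA 2 array (0.0518 and 0.055).

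Stress genes moved in both directions. Of 13 genes of the unfolded protein and integrated stress responses, 2 rose, Atf3 by 1.51 (SE 0.154, adjusted p = 0.00168) and the chaperone Dnajb9 by 0.52, the latter named after its value was seen. In the same list 3 fell: Chac1 by 1.5, Ddit3 by 1.39 and the asparagine synthetase Asns by 0.61 (adjusted p 0.022 to 0.0262). Adjusted over the list alone, 2 were higher and 4 lower. Of 18 cell cycle genes, Ccnd1, a G1 cyclin, rose by 0.70 and Cdk1 fell by 0.28, while 16 did not pass, Aurkb (0.29) and E2f1 (-0.28) among them. Of 9 ERK feedback genes, Egr1 fell by 0.79 (SE 0.134, adjusted p = 0.0092), while Spry4 (-0.43), Fos (-0.39) and Dusp6 (0.30) did not pass; over the list alone 2 were lower. Of 11 measured interferon response genes, Bst2 fell by 0.95 (SE 0.205, adjusted p = 0.0234), and Cxcl10 (0.36), Ifih1 (-0.28) and Irf7 (-0.26) did not pass.

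None of these 4 lists was shifted (camera adjusted p = 0.657 for stress, 0.687 for cell cycle, 0.179 for ERK feedback and 0.978 for interferon). Their counts stand beside 10.3% of all genes tested that passed. For the cell cycle list (median level 11.2) the nearer share is the 16.1% at levels of 9 to 13. With the replicate block Spry4 (adjusted p = 0.0184), Fos (0.0465), Dusp6 (0.0152) and Cxcl10 (0.043) passed, and the counts were 2 higher and 6 lower for stress, 1 and 3 for ERK feedback, and 1 and 1 for interferon. Atf3 kept its call without any 1 array. Without mock replicate 2, Dnajb9, Chac1, Ddit3, Asns, Ccnd1, Cdk1, Egr1 and Bst2 did not pass (adjusted p 0.073 to 0.196), nor did Dnajb9, Chac1, Cdk1, Egr1 and Bst2 without mock replicate 1 (0.0606 to 0.225). Without siRNA 2 replicate 1 Chac1, Ddit3, Asns, Ccnd1 and Cdk1 did not pass (0.055 to 0.0835), without siRNA 2 replicate 2 Dnajb9, Ddit3, Asns, Cdk1 and Bst2 (0.0514 to 0.127), and Cdk1 did not pass without either siRNA 3 array (0.054 and 0.121). The change of Ddit3 was -0.82 without mock replicate 2, and Cdk1 did not pass after repeated quantile normalization (0.0595) or median centring (0.0743).

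Each siRNA alone was then set against mock. With siRNA 2 the largest rises were those of Atp5g1 (2.80), Bhmt (2.73), Cryab (2.49), Foxa1 (2.42) and Rps15a (2.10), and the largest falls those of Diaph2 (-2.18), Lpcat3 (-2.15), Tex14 (-2.14), Clybl (-2.08) and Mettl23 (-2.0). With siRNA 3 Atp5g1 (2.88), Foxa1 (2.15), Fbp2 (2.07), Hnrnpd (2.01) and Ccdc113 (2.0) rose most, and Lpcat3 (-2.33), Tex14 (-2.20), Stmn2 (-2.09), Clybl (-1.96) and Fhod3 (-1.92) fell most. The adjusted p of these genes lay between 0.0012 (Atp5g1 with siRNA 2) and 0.0172 (Tex14 with siRNA 3). In all, 1057 genes passed with siRNA 2 (445 higher, 612 lower) and 877 with siRNA 3 (345 higher, 532 lower). Bhmt did not pass with siRNA 3 (1.44, adjusted p = 0.12), and its difference between the siRNAs did not pass either (adjusted p = 0.984). With the replicate block the counts were 2624 and 2156. With only the arrays compared in the model, 526 genes passed with siRNA 3 and 1099 with siRNA 2. Leaving out 1 array gave 66 genes with siRNA 2 without its replicate 2, 396 without its replicate 1, 215 without mock replicate 2 and 674 without mock replicate 1. For siRNA 3 it gave 287 without its replicate 2, 455 without its replicate 1, 529 and 526 without siRNA 2 replicates 1 and 2, 93 without mock replicate 2 and 573 without mock replicate 1. With siRNA 2, Bhmt, Foxa1, Diaph2 and Tex14 did not pass without its replicate 2 (adjusted p 0.0519 to 0.103), Tex14 without its replicate 1 (0.0994) or mock replicate 2 (0.0939), and Bhmt without either mock array (0.0653 and 0.0655). With siRNA 3, Foxa1 (0.063), Ccdc113 (0.054) and Tex14 (0.109) did not pass without mock replicate 2.

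The difference between the siRNAs was tested directly. No gene passed in limma (0 of 15267, smallest adjusted p = 0.984), with 644 genes at an unadjusted p under 0.05 (4.22%). With the replicate block 0 genes passed as well, with 1309 at an unadjusted p under 0.05. The genes with the smallest p, which did not pass, were higher with siRNA 2 for Hsd3b1 (0.67), Cdhr2 (0.64), Vnn1 (0.78), Cd200 (0.68) and Vstm5 (0.73), and lower with siRNA 2 for Saa2 (-0.71), Man2b1 (-0.52), Ankrd11 (-0.53), Cdh1 (-0.40) and Ifitm3 (-0.52). The 95% interval of the difference, unadjusted for the number of genes, had a median half-width of 0.317. The adjusted threshold asks for larger differences than that, and those of Vnn1 (0.78) and Vstm5 (0.73) did not pass. The 0 genes therefore do not exclude differences of this size between the siRNAs.

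The changes with both siRNAs were correlated across genes at Pearson r = 0.875 (covariance 0.0942), where genes are not independent replicates. Unchanged groups against shared mock arrays gave a mean r of 0.499 and a covariance of 0.0119, so the covariance above that of the shared mock arrays was 0.0824. The simulated arrays were not paired by replicate number, so these no-change values ignore the pairing. Within replicate 1 the correlation was 0.763 and within replicate 2 it was 0.867. With each siRNA set against a different mock array, which leaves 1 array per group and no shared control, it was 0.633 and 0.686. Both siRNAs called 272 genes higher and 418 lower, against 10.1 and 21.3 for independent lists of the same lengths. Simulated unchanged groups gave 0 in each direction in 20 draws, which the adjusted threshold nearly fixes and which is no measure of the overlap. The calls were not split by mock array, so part of the excess of shared calls may come from the shared controls.

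**Figure D4:**
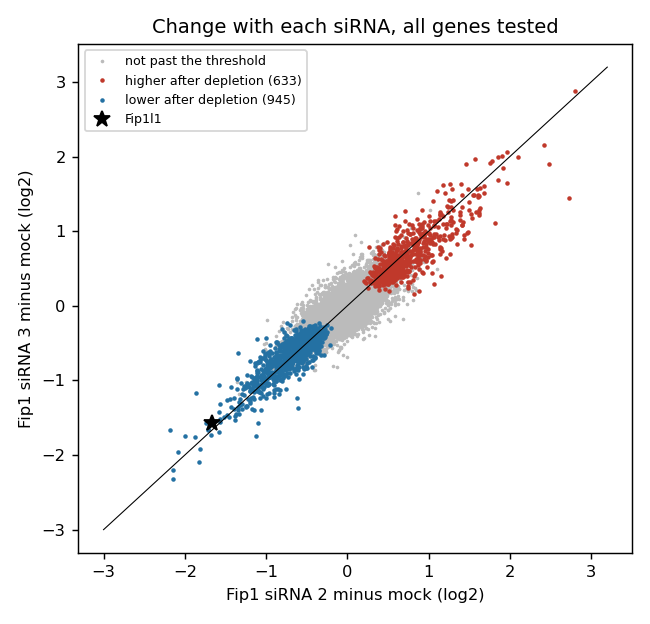
Log2 difference from mock with Fip1 siRNA 2 (horizontal axis) and Fip1 siRNA 3 (vertical axis) for the 15267 genes tested; red and blue mark the 633 higher and 945 lower genes for the mean of both siRNAs, the star is Fip1l1, and the line marks equal change. Pearson r over the genes was 0.875, against 0.499 for simulated unchanged groups with shared mock arrays and no pairing by replicate number.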

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

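The tests of the unnamed probe sets, of lists between the siRNAs, of saturation, of the p53 explanations, of the ribosomal list against the mock arrays as an explanation, and of the ratio of changes between replicates were chosen after the results were seen.

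A signal appeared in probe sets that no comparison used. Of the 1286 unnamed probe sets, 41 were higher and 62 lower after depletion in a limma fit of all 16556 probe sets (8.01%, against 9.88% of the named ones). The siRNAs differed in a pair of lists, although 0 single genes passed in limma (644 at an unadjusted p under 0.05). The mean of the replication-dependent histone list was lower with siRNA 2 than with siRNA 3 by a log2 difference of -0.276 (8 of 9 members, camera adjusted p = 0.00159, or 0.529 with an estimated correlation). That of the primitive endoderm list was lower by -0.172 (13 of 18 members, adjusted p = 0.0327, or 0.529 with an estimated correlation). Without siRNA 2 replicate 1 the differences of these lists were -0.181 and -0.0663, and without siRNA 3 replicate 2 they were -0.11 and -0.0351. Neither list passed in these fits. Without siRNA 2 replicate 2 the differences were -0.371 and -0.278, and without siRNA 3 replicate 1 they were -0.443 and -0.309. The ERK feedback list passed with the replicate block alone (-0.116, adjusted p = 0.0452, against 0.0812 without the block), and with an estimated correlation its adjusted p was 0.42 with the block and 0.529 without. No group has 4 arrays, so single outlying arrays were not tested.

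Of the ribosomal protein list, 10 of the 13 dimmer members rose after depletion (median of the 13: 1.16). The risers had mean levels from 5.09 (Rpsa) to 12.55 (Rpl14), with Rps15a at 6.52, Rpl17 at 6.83 and Rpl21 at 8.11. The array medians were 6.08 to 6.12. The 10 brightest members (level above 13) lay within 0.115 of 0 and did not pass under any scaling run. Their median of -0.0363 was 0.0215 after repeated quantile normalization. A rise of ribosomal protein mRNA as a whole is therefore not shown. A general rise of probe sets at these levels is argued against: only 0.01% of 10000 level-matched random lists had a mean as high as 0.528, the smallest share they can give. A single mock array is argued against too, since the lower list mean without 1 mock array was 0.493 and the call with the preset correlation held without either (with all arrays the adjusted p was 0.276 with an estimated correlation). Saturation may hide a rise of the bright members: outside the list 8.16% of genes above 13 passed, against 16.1% at levels of 9 to 13, which decides neither way. Readings of related copies or of altered transcript ends, the latter a biological candidate after loss of a polyadenylation factor, stay open, as probe positions were not used here.

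Of 15 p53 targets, 7 rose and 0 fell after depletion, and the list was shifted with the preset correlation alone (adjusted p = 0.276 with an estimated correlation). With siRNA 2 the list mean was 0.415 and with siRNA 3 it was 0.485, a difference of -0.0701 (camera adjusted p = 0.235). Each siRNA shifted the list with the preset correlation (larger camera adjusted p = 2.04e-05). These values argue against an effect of the sequence of 1 siRNA alone. The outcome set out for excluding it was not met. With an estimated correlation the camera adjusted p was 0.351 with siRNA 2 and 0.225 with siRNA 3 (unadjusted 0.0318 and 0.0187). No other fixed list had a lower adjusted p in that version with either siRNA. The estimated version uses the residual degrees of freedom alone, so a small p is hard to reach. A miss in it therefore decides neither way. Both siRNAs share the mock arrays, so a difference of these arrays would enter both means. An interferon response to siRNA could not be excluded by the outcome set out. The interferon list had a median of -0.00816, but its members had an SD of 0.345, against a p53 median of 0.284. That SD is the spread between members, widened by the fall of Bst2 (-0.954), and is no error of the median. Of 11 measured members 0 rose and 1 fell (1 and 1 with the block). Their median level was 4.26, where changes may be compressed. An effect of any siRNA as such cannot be told apart from Fip1 depletion, because 0 arrays carry a control siRNA. A response to Fip1 loss itself remains a candidate explanation.

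Over the 1578 genes called, the median ratio of the change in replicate 2 to that in replicate 1 was 1.27, and 76.7% had the larger change in replicate 2. The test of that difference for each gene passed for 0 genes in limma (679 at an unadjusted p under 0.05, smallest adjusted p = 0.999). That test took both siRNAs as 1 group with 1 mock array per replicate, so it holds no measure of the spread between mock arrays. The siRNA arrays of replicate 2 lay 0.054 further in the direction of the change than those of replicate 1, and the mock arrays had a median difference of -0.0842 in that direction, within a total gap of 0.151. This falls between the outcomes set out for the mock array alone and for its exclusion, so its part stays open. Deeper depletion may contribute (Fip1l1 ratio 1.45) but cannot be told apart from other differences between the replicates, of which the labels give only the number and a shared title suffix.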

How the results depend on the processing

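The alternatives were fixed before the data were examined, except the fit of all probe sets, the lists of at least 3 members, and the block with an estimated correlation, which were chosen after seeing the data. The replicate block raised the counts of changed genes from 1578, 1057 and 877 to 3080 (mean), 2624 (siRNA 2) and 2156 (siRNA 3). It gave 15 more calls among 126 named gene results and ended none of them. It also added Mrpl1, the trophectoderm and histone lists and the ERK feedback difference between the siRNAs. Of the genes named for the replicate difference, Atf4, Herpud1 and Trib3 were lower after depletion with the block (limma adjusted p = 0.000559, 0.00492 and 0.00472). Without the block they did not pass (0.0539, 0.189 and 0.214). A 2-fold minimum left 244 genes by construction, and only the arrays compared gave 526 for siRNA 3 and 1099 for siRNA 2; the cause was not tested. Of 4 lists called, 1 has a single measured gene (3 of the lists with at least 3 members were called). Of all 17 lists, 0 were called with an estimated correlation, 0 with the block and an estimated correlation, and 7 with fry. The estimated version uses the residual degrees of freedom alone, which raises p also without correlation between genes. The cleavage factor list had an estimated correlation of -0.00574, below the preset 0.01. Its unadjusted camera p still went from 0.0171 to 0.0811. The 0 calls therefore do not show that correlation between genes undoes the shifts. The cause of the fry count was not tested. Leaving out 1 array gave 305 to 1368 genes for the mean, 66 to 1094 for siRNA 2, 93 to 573 for siRNA 3, 4 to 7 lists, and correlations of 0.765 to 0.902 between the siRNAs. The lowest counts were those without mock replicate 2 (305 and 93) and without siRNA 2 replicate 2 (66). These fits leave 1 group with 1 array, which is assumed to vary like the others. Of the 84 called gene results named, 44 kept their call in all 6 such fits and 40 lost it in at least 1, 36 of them without mock replicate 2; 0 reversed. Fip1l1 passed in every alternative run (log2 change -1.49 to -1.75 without 1 array). The p53, ribosomal protein and sterol lists passed in every setting with the preset correlation. Filters, repeated normalization, centring, the prior, added background and the pooled siRNA group moved each count of genes by less than 1.5 times, and the difference between the siRNAs stayed at 0 genes in limma in each setting (644 at an unadjusted p under 0.05 without the block). Among the named genes these settings ended calls of Cdk1, Dppa2 and Gsc alone, the latter pair without the trend of the prior and Gsc also with added background. Probe sets near background carry compressed changes, which limits what dim genes can show.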

Other observations

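The tests in this part were chosen after the data were seen.

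Among genes of the mitochondrial ribosome those that passed fell, except 1 that rose after median centring and 1 with the replicate block. Of 71 measured genes with symbols starting in Mrpl or Mrps, 10 fell, 0 rose and 59 had a negative difference (median -0.152). Mrpl54 fell by 0.82 (SE 0.123, adjusted p = 0.00611), Mrps35 by 0.70 (SE 0.0901, adjusted p = 0.00331), Mrps7 by 0.52 and Mrps30 by 0.48; these genes are named after their values were seen. The replicate block gave 18 lower and 1 higher, Mrpl1 (0.41, adjusted p = 0.0108), named after its value was seen. After median centring 5 fell and 1 rose (median -0.126), and after repeated quantile normalization 7 fell and 0 rose (median -0.131). Without 1 array the median stayed between -0.138 and -0.165, but fewer genes fell: 5 and 3 without siRNA 2 replicates 1 and 2, 4 and 3 without siRNA 3 replicates 1 and 2, and 3 and 1 without mock replicates 1 and 2. Among 212 families of at least 10 genes that share a symbol stem, Mrpl was the only one past the threshold (46 genes, 6 lower, camera adjusted p = 0.0163), and with an estimated correlation it did not pass (unadjusted p = 0.0712, adjusted p = 1). The call also ended without siRNA 2 replicate 2 (adjusted p = 0.0604), siRNA 3 replicate 2 (0.0614) or mock replicate 2 (0.084). The Mrps family did not pass (25 genes, 4 lower, adjusted p = 0.121). Of level-matched random lists, 0.02% had a mean as low as the 71 genes. These genes were singled out in the same data and the random lists ignore correlation between genes, so that share is no support for the fall. Mrps35 kept its call without any 1 array, while without mock replicate 2 Mrpl54, Mrps7 and Mrps30 did not pass (adjusted p 0.0566 to 0.163), nor did Mrps7 and Mrps30 without siRNA 2 replicate 2 (0.0706 and 0.0527) and Mrps7 without mock replicate 1 (0.129) or siRNA 3 replicate 2 (0.0605).

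Replicates 1 and 2 differed in epiblast and primitive endoderm markers, with list medians of the same sign in all 3 groups. In the limma fit with the replicate block, 382 genes differed between the replicates, 161 higher and 221 lower in replicate 2. The count was 207 and 216 without siRNA 2 replicates 1 and 2, and 204 and 193 without mock replicates 1 and 2. Of 15 post-implantation epiblast genes, 6 were lower in replicate 2 and 0 higher, among them Pou3f1 (-1.24), Sall2 (-0.96) and Fgf5 (-0.84). Of 18 primitive endoderm genes, 5 were higher and 0 lower, among them Sox7 (0.80), Sox17 (0.65) and Gata6 (0.64). The epiblast list had a median replicate difference of -0.182, -0.392 and -0.577 in the siRNA 2, siRNA 3 and mock groups, and the primitive endoderm list of 0.234, 0.14 and 0.389. The camera adjusted p was 1.62e-09 and 8.38e-06, or 0.313 for both with an estimated correlation. With the preset correlation both lists passed under each scaling and without any 1 array; without either mock array 4 epiblast genes and 1 primitive endoderm gene passed, and without either siRNA 2 array or siRNA 3 replicate 2 the latter count was 3. Of 13 stress genes 4 were higher, Chac1 (0.78), Trib3 (0.71), Herpud1 (0.53) and Atf4 (0.38), and Sesn2 was lower (-0.74). The stress list (median 0.284, adjusted p = 0.00435) and the histone list (0.345, adjusted p = 0.00348) were higher, both with an adjusted p of 0.313 with an estimated correlation. The sterol synthesis list was lower (-0.129, adjusted p = 0.0337, or 0.393 with an estimated correlation). The other lists did not pass, with an adjusted p of 0.105 for trophectoderm, 0.702 for mesoderm and 0.534 for neuroectoderm and for fibroblasts. The genes named for the replicate difference were chosen after their values were seen, and they and these 3 lists were not refitted without single arrays. A test of whether the effect of depletion differed between the replicates passed for 0 genes in limma, with 679 at an unadjusted p under 0.05. It took both siRNAs as 1 group, with 1 mock array per replicate. Its spread comes from the siRNA arrays alone, so the 0 genes do not show an equal effect in both replicates.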
